A study of Arabidopsis thaliana with 18 samples.

How the data were processed

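RNA-seq of whole 7-day-old Arabidopsis seedlings was analysed in 18 libraries, 3 for each of the 6 combinations of genotype (Col, h3.3kd, elf7-3) and temperature (21 or 27 °C). Total RNA had been used with a NEBNext Ultra kit. The submitters' processing notes name fastp 0.20.1, HISAT2, HTSeq 0.11.2 and DESeq2 1.26.0 without roles, and the build TAIR10, and the row names carry the annotation Araport11.447. The table deposited by the authors holds TPM (transcript abundances scaled to a fixed sum per library), each column summing to 1000000 over 27655 genes, with 88 chloroplast and 122 mitochondrial genes included. How TPM were computed, the gene lengths used and the library strandedness are not stated. All 18 columns matched the labels of 1 library each, and 0 were left unmapped. The labels give no batch or date and do not say that replicates were grown apart, so p-values measure only the spread between these libraries, which may be technical.

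The values of 1838 genes with low levels were tested for whole reads: in 98.7% of them all libraries lay within 0.05 reads of whole numbers at 1 gene length, and in 0% after random rescaling. Depth was estimated from the exon lengths of the NCBI annotation of TAIR10.1, in which 27445 of 27655 loci were found. As only about 31% of low values became whole with these lengths, the 6.69e+06 to 1.09e+07 reads per library are approximate. No interval from counts was computed. Coordinates and product names are from TAIR10.1.

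Genes with at least 1 TPM in at least 3 libraries were kept, 20048 in all. Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and a mean-dependent prior, leaving 12 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, over all genes of a comparison, two-sided. The 9 comparisons were 27 against 21 °C in each genotype, each mutant against Col at each temperature, and the 2 interactions, which are the mutant's warmth response minus that of Col. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and plots.

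The tests, comparisons, alternatives and 20 gene lists were chosen before the data were examined. The lists hold the targeted genes, H3.1 genes, H3.3 and H2A.Z deposition and removal, the Paf1 complex, warm and shade growth regulators, auxin synthesis, auxin response, cell wall expansion, gibberellin and brassinosteroid, heat shock, the circadian clock, flowering time, photosynthesis, immunity and jasmonate, cold and abscisic acid, flavonoid and anthocyanin, cell cycle, root markers, seed storage and embryo, and floral organ identity. The last 3 stand for organs or stages that whole seedlings could hold in different shares. Each list was compared with all other genes by limma's camera with a correlation of 0.01 and, as an alternative, an estimated correlation, with adjusted p over the 20 lists. Of 180 list results 48 were called, and 10 of these held with an estimated correlation. They include the list of targeted genes in h3.3kd, a line made to reduce H3.3. Members called over all genes and adjusted over the list alone were counted.

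Genes were named by a rule fixed beforehand: the targeted genes, the 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 5 TPM whose groups did not overlap (for interactions, called only), and up to 4 called members of each list with the largest changes. Where several could serve as an example, members whose call held in the alternatives were preferred, a choice made after seeing them. Log2 values are given to 2 decimals, some to 1. They are of TPM + 1, which shrinks changes of genes at low levels. The order of the largest changes and the 2-fold counts depend on this. Near-identical genes, such as the H3 genes, the SAUR genes and the LHCB1 genes, may share reads.

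Overlaps of both mutants were compared with independent calls and with 20 simulations of unchanged groups that shared the Col libraries, which could not be split as they number 3. Warmth responses were also compared on genes chosen in the remaining genotype. Organelle shares were compared by exact two-sided permutation, for which the smallest p with 3 against 3 is 0.1. The alternatives chosen beforehand were a pseudocount of 0.1, no filter and a filter at 5 TPM, median-of-ratios scaling, organelle genes removed, library weights, a replicate block, only the compared groups, a 2-fold change and leaving out each library. Fits on estimated reads with limma's voom were added after seeing the data, as were 257 product families of at least 8 genes tested by camera in the 9 comparisons. Each comparison was recounted in other splits of its libraries, 10 for 2 groups and 100 drawn relabellings for interactions. Recovery was tested on simulated data, in which 200 of 20048 genes were changed.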

Results

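Transcript levels were measured by RNA-seq in 18 libraries of 7-day-old Arabidopsis thaliana seedlings raised in short days at 21 °C or 27 °C. The 3 genotypes were the wild type Col, the line h3.3kd with reduced histone variant H3.3, and elf7-3, a mutant of ELF7, a subunit of the Paf1 complex that accompanies RNA polymerase II. Each genotype had 3 libraries at each temperature. The study asked how chromatin takes part in thermomorphogenesis, the elongation growth of plants in moderate warmth, with H2A.Z removal and H3.3 deposition as its subjects. The deposited table held 27655 genes as TPM (transcript abundances scaled to a fixed sum per library). Its low values implied between 6.69e+06 and 1.09e+07 gene-assigned reads per library, as an approximate figure, since the gene lengths behind the table were not stated. Between 18563 and 19225 genes reached 1 TPM per library. The first principal component held 37.4% of the variance and the second 28.1%. On the first, every genotype's group mean was higher at 27 °C than at 21 °C. On the second, h3.3kd had lower group means than Col and elf7-3 at both temperatures. Values after a gene name below are its locus at first mention and its log2 fold change ± standard error, from 3 libraries against 3, or for interactions from 4 groups of 3 (n = 3 per group). Adjusted p-values are from limma, two-sided.

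The targeted genes came first. HTR8, 1 of the genes for H3.3, lies on chromosome 5 from 3472405 to 3473570 (coordinates on TAIR10.1), and its level in Col was 343 ± 12.7 TPM (SD, n = 3) at 21 °C and 190 ± 6.53 at 27 °C. In h3.3kd it was 18.8 ± 1.73 and 17 ± 2.4 TPM, a log2 fold change against Col of -4.12 ± 0.077 at 21 °C and -3.38 ± 0.077 at 27 °C. HTR4 and HTR5, which also encode H3.3, lie side by side on chromosome 4 from 18555532 to 18557106 and from 18557149 to 18558945. HTR4 fell from 427 ± 3.13 TPM in Col to 44.7 ± 0.887 in h3.3kd at 21 °C (-3.23 ± 0.047) and from 338 ± 8.32 to 54.2 ± 3.75 at 27 °C (-2.62 ± 0.047). HTR5 fell less, from 601 ± 10.1 to 270 ± 9.67 TPM at 21 °C (-1.15 ± 0.052) and from 447 ± 22.6 to 265 ± 6.28 at 27 °C (-0.75 ± 0.052). In elf7-3 the H3.3 genes also differed from Col: HTR4 was lower (-0.56 ± 0.047 at 21 °C, -0.54 ± 0.047 at 27 °C), and HTR5 (0.39 ± 0.052, 0.53 ± 0.052) and HTR8 (0.22 ± 0.077, 0.39 ± 0.077) were higher. In elf7-3, HTR4 was 289 ± 8.76 and 232 ± 7.18 TPM, HTR5 790 ± 51.1 and 646 ± 18.9, and HTR8 400 ± 14.9 and 248 ± 8.12, at 21 and 27 °C. The 3 genes have similar coding sequences, so reads may have been shared between them. The HTR8 call in elf7-3 at 21 °C was lost when any Col library, or replicate 2 or 3 of elf7-3, at 21 °C was left out (0.19 to 0.24), with a replicate block (adjusted p = 0.0558) and with no filter (adjusted p = 0.0508).

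ELF7 lies on chromosome 1 from 30000538 to 30004083. Its level was 29.2 ± 1.72 TPM in Col and 9.04 ± 0.473 in elf7-3 at 21 °C (-1.59 ± 0.070), and 40.7 ± 0.475 and 13.0 ± 0.486 at 27 °C (-1.57 ± 0.070). In h3.3kd it was 28.1 ± 1.63 at 21 °C and 36.3 ± 2.73 at 27 °C, and it was not called against Col (-0.05 ± 0.070 and -0.16 ± 0.070), except at 27 °C with library weights (-0.19) or without h3.3kd replicate 1 (-0.20). Warmth itself raised ELF7 in Col (0.46 ± 0.070), h3.3kd (0.36 ± 0.070) and elf7-3 (0.48 ± 0.070). Warmth lowered HTR8, HTR5 and HTR4 in Col (-0.85 ± 0.077, -0.43 ± 0.052 and -0.34 ± 0.047) and in elf7-3 (-0.69 ± 0.077, -0.29 ± 0.052 and -0.32 ± 0.047). In h3.3kd HTR4 rose (0.27 ± 0.047), while HTR8 (-0.11 ± 0.077) and HTR5 (-0.03 ± 0.052) were not called. The warmth response of all 3 H3.3 genes was more positive in h3.3kd than in Col by the interaction test: 0.74 ± 0.11 for HTR8, 0.61 ± 0.067 for HTR4 and 0.40 ± 0.073 for HTR5. For the 4 targeted genes as a list, the h3.3kd difference at 21 °C had adjusted p = 1.49e-06 by camera, a test of a list against all other genes, and adjusted p = 0.0418 with an estimated correlation. At 27 °C these were 3.23e-04 and adjusted p = 0.116, and for the h3.3kd interaction 0.00265 and adjusted p = 0.239. The line was made to reduce H3.3, so a lower level of this list in h3.3kd checks the line and is no finding. The more positive warmth response of the list in h3.3kd cannot be told apart from that reduction.

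**Figure D1:**
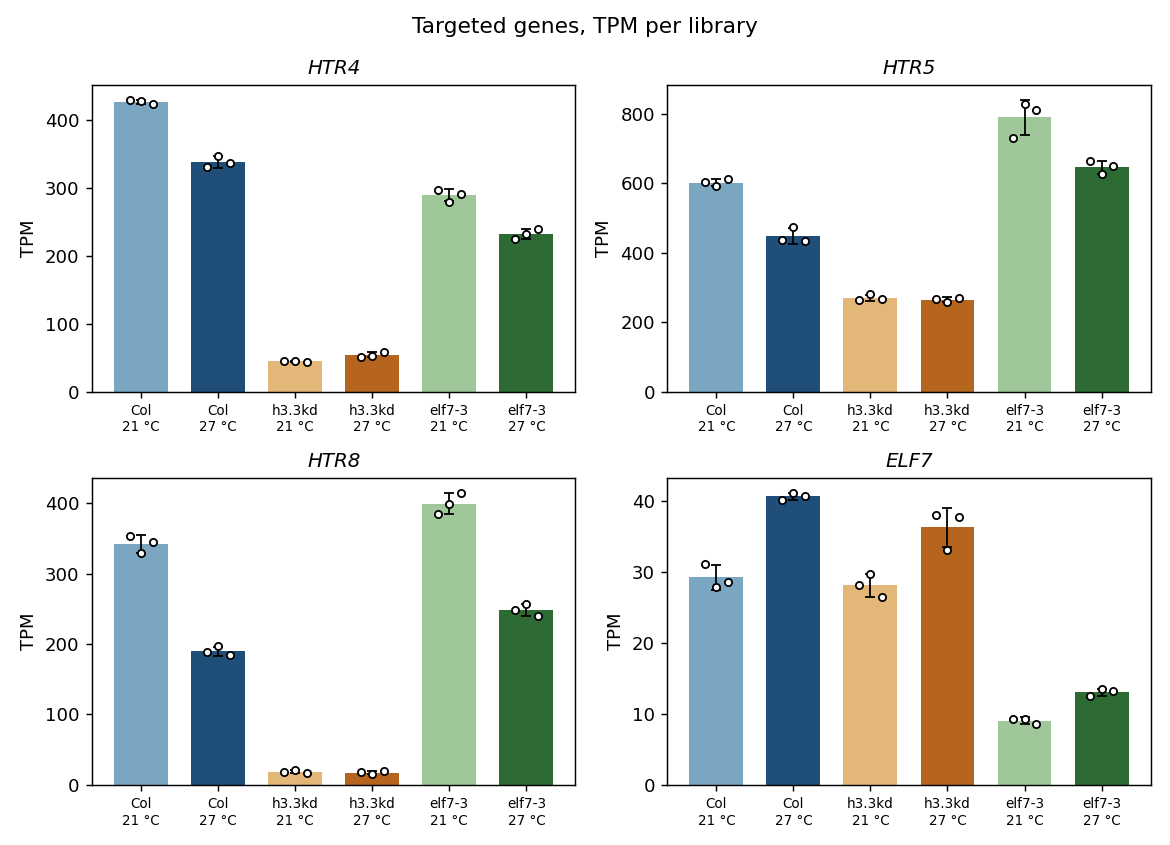
TPM of the 3 H3.3 genes and of ELF7 in each of the 6 groups. Bars are means, lines are SDs and circles the 3 libraries. HTR8 averaged below 20 TPM in h3.3kd at both temperatures, and ELF7 was lowest in elf7-3.

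Warmth in Col asked which genes respond to 27 °C in the wild type. The largest rise belonged to AT5G22500 (4.80 ± 0.27), annotated as a fatty acid reductase, followed by AT5G44440 (4.34 ± 0.37), a berberine bridge enzyme-like protein, FLP1 (AT4G31380, 3.93 ± 0.36), a flowering-promoting factor-like protein, AT5G62280 (3.70 ± 0.25), LAC2 (AT2G29130, 3.52 ± 0.20), a laccase, and HSP90.1 (AT5G52640, 3.39 ± 0.13), a chaperone. The largest falls were LHCB1.1 (AT1G29920, -4.76 ± 0.30), a chlorophyll-binding antenna protein with near-identical sister genes, SESA3 (AT4G27160, -3.32 ± 0.42), a seed storage albumin, GH9B15 (AT4G23560, -3.20 ± 0.19), AT5G46960 (-3.18 ± 0.22), AT4G30650 (-3.15 ± 0.22) and BIP3 (AT1G09080, -3.05 ± 0.21), a chaperone of the endoplasmic reticulum. Auxin response genes rose as a group: 21 of 25 tested members rose and 0 fell (21 and 0 adjusted over the list alone). Auxin response genes had adjusted p = 4.03e-07 by camera and adjusted p = 0.124 with an estimated correlation. Among them were IAA29 (AT4G32280, 3.1 ± 0.20), on chromosome 4 from 15583332 to 15584903, IAA19 (AT3G15540, 2.31 ± 0.19) and IAA6 (AT1G52830, 2.11 ± 0.31), which encode auxin-induced repressors, and SAUR22 (AT5G18050, 2.64 ± 0.28), 1 of a set of near-identical SAUR genes. Of the auxin synthesis genes, 5 of 8 rose and 1 fell (5 and 1 adjusted over the list alone): YUC8 (AT4G28720, 3.1 ± 0.26), on chromosome 4 from 14192569 to 14194302, YUC9 (AT1G04180, 1.98 ± 0.22) and YUC2 (AT4G13260, 1.2 ± 0.14) encode flavin monooxygenases of that pathway, and TAA1 (AT1G70560, -1.0 ± 0.11), which acts in the step before, fell. This list was not called (camera adjusted p = 0.23). Of the warm and shade growth regulators, 11 of 18 rose and 2 fell (11 and 2 adjusted over the list alone), with HFR1 (AT1G02340, 1.75 ± 0.12), PIF5 (AT3G59060, 1.75 ± 0.12), PRE1 (AT5G39860, 1.58 ± 0.23) and PRE6 (AT1G26945, 1.5 ± 0.16), all helix-loop-helix proteins of the light and growth network, at the top. Warm and shade growth regulators had adjusted p = 0.0438 by camera and adjusted p = 0.124 with an estimated correlation. Heat shock genes also rose: 18 of 23 tested members rose and 1 fell (19 and 1 adjusted over the list alone), with HSP70-4 (AT3G12580, 2.87 ± 0.15), HSP23.5 (AT5G51440, 2.50 ± 0.17) and ROF2 (AT5G48570, 2.24 ± 0.17) after HSP90.1. Heat shock genes had adjusted p = 1.67e-05 by camera and adjusted p = 0.124 with an estimated correlation.

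All clock genes tested in Col rose at 27 °C: 14 of 14 tested members rose and 0 fell (14 and 0 adjusted over the list alone). Clock genes had adjusted p = 1.62e-06 by camera and adjusted p = 0.0407 with an estimated correlation. The largest changes were LUX (AT3G46640, 2.22 ± 0.074) and GI (AT1G22770, 2.02 ± 0.17), evening-phased genes, and RVE1 (AT5G17300, 1.85 ± 0.16) and RVE8 (AT3G09600, 1.55 ± 0.17). The labels do not give the hour of harvest. Of gibberellin and brassinosteroid genes, 12 of 20 rose and 0 fell (12 and 0 adjusted over the list alone), with GA20OX1 (AT4G25420, 2.02 ± 0.23), a gibberellin synthesis enzyme, GA2OX6 (AT1G02400, 1.66 ± 0.14), a gibberellin-inactivating enzyme, and BRI1 (AT4G39400, 1.16 ± 0.070), the brassinosteroid receptor. Gibberellin and brassinosteroid genes had adjusted p = 0.00304 by camera and adjusted p = 0.124 with an estimated correlation. All 5 H3.1 genes, which encode the replication-coupled form of H3, fell (0 of 5 rose and 5 fell, or 0 and 5 adjusted over the list alone), HTR13 (AT5G10390, -0.93 ± 0.15) and HTR2 (AT1G09200, -0.87 ± 0.088) the most. H3.1 genes had adjusted p = 0.00463 by camera and adjusted p = 0.141 with an estimated correlation. Of cell cycle genes, 1 of 19 rose and 9 fell (1 and 9 adjusted over the list alone), with CYCB1;1 (AT4G37490, -0.93 ± 0.15), a mitotic cyclin, and MCM7 (AT4G02060, -0.57 ± 0.097), a replication helicase subunit, among those that fell. Cell cycle genes had adjusted p = 0.00621 by camera and adjusted p = 0.362 with an estimated correlation. Root markers, which stand for another organ in these whole seedlings, moved with the growth genes: 10 of 16 tested members rose and 0 fell (10 and 0 adjusted over the list alone), among them IRT1 (AT4G19690, 2.50 ± 0.28), a root iron transporter, and CASP5 (AT5G15290, 2.23 ± 0.16) and CASP4 (AT5G06200, 1.5 ± 0.20), Casparian strip proteins. Root markers had adjusted p = 0.00621 by camera and adjusted p = 0.282 with an estimated correlation.

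The other lists were not called in Col. Of cold and abscisic acid genes, 7 of 13 rose and 6 fell (7 and 6 adjusted over the list alone, with camera adjusted p = 0.679): the cold-regulated COR15B (AT2G42530, -3.02 ± 0.30) and COR15A (AT2G42540, -2.56 ± 0.33) fell, and RD29B (AT5G52300, 2.1 ± 0.10), an abscisic acid response gene, rose. The list's median of 0.35 was positive and its mean of -0.27 negative. Of photosynthesis genes, 14 of 25 rose and 8 fell (14 and 8 adjusted over the list alone, with adjusted p = 0.367), with LHCB4.2 (AT3G08940, 2.57 ± 0.15) and LHCB2.1 (AT2G05100, 2.52 ± 0.12), antenna genes, among the rises. Of immunity and jasmonate genes, 5 of 16 rose and 3 fell (5 and 3 adjusted over the list alone, with adjusted p = 0.766, with a median of 0.13 and a mean of -0.074), and PR5 (AT1G75040, -2.35 ± 0.24), a pathogenesis-related gene, fell. Of cell wall expansion genes, 8 of 19 rose and 4 fell (8 and 4 adjusted over the list alone, with adjusted p = 0.607), EXPA8 (AT2G40610, 2.36 ± 0.15), an expansin, rising the most. Flowering time genes (2 of 14 rose and 4 fell, or 2 and 4 adjusted over the list alone; adjusted p = 0.381) included SOC1 (AT2G45660, -1.5 ± 0.17), a floral promoter that fell. Flavonoid genes (1 of 10 rose and 6 fell, or 1 and 6 adjusted over the list alone; adjusted p = 0.126) included DFR (AT5G42800, -1.19 ± 0.27). Seed storage and embryo genes (4 of 13 rose and 7 fell, or 4 and 7 adjusted over the list alone; adjusted p = 0.396) went both ways, with SESA1 (AT4G27140, -2.39 ± 0.46) and OLEO2 (AT5G40420, 2.26 ± 0.18), an oil body protein. H3.3 and H2A.Z deposition genes (5 of 15 rose and 4 fell, or 5 and 5 adjusted over the list alone; adjusted p = 0.607) included ASF1B (AT5G38110, -0.85 ± 0.13), a histone chaperone, and Paf1 complex genes (4 of 6 rose and 1 fell, or 4 and 1 adjusted over the list alone; adjusted p = 0.299) VIP5 (AT1G61040, 0.54 ± 0.071). Of 6 floral organ genes, 2 were tested and both rose, SEP3 (AT1G24260, 0.90 ± 0.19) and PI (AT5G20240, 0.73 ± 0.20) (adjusted p = 0.299). The call of warm and shade growth regulators was lost with a pseudocount of 0.1 (adjusted p = 0.0615) and with a filter at 5 TPM (adjusted p = 0.165). In total 11021 of 20048 genes were called in Col, 6589 higher and 4432 lower at 27 °C, of which 896 and 426 also changed past 2-fold. With median-of-ratios scaling the calls split into 5467 higher and 5401 lower.

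In h3.3kd the question was whether the warmth response depends on H3.3. The largest rises were the mitochondrial genes ATMG00665 (7.20 ± 0.83) and ATMG00630 (4.24 ± 0.36), followed by AT2G07722 (3.72 ± 0.32), the small chaperones HSP17.4 (AT3G46230, 3.70 ± 0.46) and HSP17.6A (AT5G12030, 3.56 ± 0.31), and AT2G07629 (3.49 ± 0.29). The organelle share was far higher in 1 library: chloroplast and mitochondrial genes took 3.66% of all TPM in h3.3kd replicate 1 at 27 °C and between 0.128% and 0.343% in the other h3.3kd libraries. Without that library the median rise of chloroplast genes went from 1.89 to 0.69, and that of mitochondrial genes from 1.68 to 1.47, with 51 of 54 called as rising before and 47 after. Mitochondrial genes alone took 0.241%, 0.0659% and 0.0804% in the 3 libraries at 27 °C and 0.0121% to 0.0145% at 21 °C. The largest falls were AT3G05727 (-5.29 ± 0.17), AT2G05510 (-4.44 ± 0.18), MIOX2 (AT2G19800, -4.12 ± 0.25), an inositol oxygenase, LHCB1.1 (-3.88 ± 0.30), AT4G22490 (-3.68 ± 0.14) and COR15A (-3.44 ± 0.33). Of auxin response genes, 21 of 25 rose and 0 fell (21 and 0 adjusted over the list alone), with SAUR22 (3.2 ± 0.28), SAUR24 (AT5G18080, 2.61 ± 0.20) and GH3.3 (AT2G23170, 2.59 ± 0.16), an auxin-conjugating enzyme. Auxin response genes had adjusted p = 6.26e-11 by camera and adjusted p = 0.038 with an estimated correlation. Of auxin synthesis genes, 5 of 8 rose and 1 fell (5 and 1 adjusted over the list alone, with adjusted p = 0.429), and YUC8 (1.84 ± 0.26) rose. Heat shock genes rose: 18 of 23 tested members rose and 0 fell (19 and 0 adjusted over the list alone), with HSP70-4 (3.01 ± 0.15) and MBF1C (AT3G24500, 2.61 ± 0.17) after the 2 small chaperones. Heat shock genes had adjusted p = 8.34e-10 by camera and adjusted p = 0.038 with an estimated correlation. Clock genes rose: 10 of 14 tested members rose and 0 fell (10 and 0 adjusted over the list alone), led by RVE8 (1.61 ± 0.17) and RVE1 (1.56 ± 0.16). Clock genes had adjusted p = 4.81e-05 by camera and adjusted p = 0.038 with an estimated correlation. Of cold and abscisic acid genes, 2 of 13 rose and 7 fell (2 and 7 adjusted over the list alone), with COR15B (-2.30 ± 0.30) and LTI30 (AT3G50970, -1.71 ± 0.19). Cold and abscisic acid genes had adjusted p = 0.0389 by camera and adjusted p = 0.636 with an estimated correlation. Of cell cycle genes, 2 of 19 rose and 10 fell (2 and 12 adjusted over the list alone), with MCM7 (-0.86 ± 0.097) and MCM6 (AT5G44635, -0.81 ± 0.12). Cell cycle genes had adjusted p = 0.0112 by camera and adjusted p = 0.622 with an estimated correlation. Root markers went both ways (4 of 16 rose and 4 fell, or 4 and 4 adjusted over the list alone; adjusted p = 0.994). In total 9192 genes were called, 5240 higher and 3952 lower, with 754 and 337 past 2-fold. With median-of-ratios scaling 4683 were higher and 4636 lower (50.3% higher). The cold and abscisic acid call was lost without replicate 1 or 3 at 21 °C or replicate 2 at 27 °C (adjusted p = 0.0502, 0.0733 and 0.103). It was also lost with a pseudocount of 0.1, a filter at 5 TPM, median-of-ratios scaling, voom on estimated reads and only the groups compared (adjusted p = 0.0518 to 0.12).

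In elf7-3 the same question concerned the Paf1 complex. Clock genes rose: 12 of 14 tested members rose and 0 fell (12 and 0 adjusted over the list alone), with GI (2.40 ± 0.17) and LUX (2.08 ± 0.074). Clock genes had adjusted p = 3.49e-06 by camera and adjusted p = 0.0414 with an estimated correlation. Heat shock genes rose: 15 of 23 tested members rose and 0 fell (15 and 0 adjusted over the list alone), with HSP90.1 (2.54 ± 0.13) and HSP70-4 (2.45 ± 0.15). Heat shock genes had adjusted p = 8.53e-05 by camera and adjusted p = 0.195 with an estimated correlation. Of auxin response genes, 15 of 25 rose and 0 fell (15 and 0 adjusted over the list alone), with SAUR19 (AT5G18010, 1.11 ± 0.25) and IAA19 (0.93 ± 0.19). Auxin response genes had adjusted p = 0.0168 by camera and adjusted p = 0.504 with an estimated correlation. Of auxin synthesis genes, 1 of 8 rose and 1 fell (1 and 1 adjusted over the list alone, with adjusted p = 0.772), the fall being TAA1 (-0.53 ± 0.11). Of H3.1 genes, 0 of 5 rose and 4 fell (0 and 4 adjusted over the list alone). H3.1 genes had adjusted p = 0.0168 by camera and adjusted p = 0.252 with an estimated correlation. Root markers went both ways (1 of 16 rose and 2 fell, or 1 and 2 adjusted over the list alone; adjusted p = 0.66). Among the largest rises were AT1G04560 (3.45 ± 0.13), ATMG00665 (3.09 ± 0.83), ECP63 (AT2G36640, 3.01 ± 0.14), a late embryogenesis abundant protein, AT1G54870 (3.0 ± 0.11) and AT2G15880 (2.97 ± 0.14). The largest falls were LHCB1.1 (-5.44 ± 0.30), AT2G25510 (-4.23 ± 0.29), AIG1 (AT1G33960, -3.67 ± 0.18), AT5G42530 (-3.62 ± 0.29), AT5G18840 (-3.37 ± 0.23) and AT3G22235 (-3.16 ± 0.34). Of cold and abscisic acid genes, 5 of 13 rose and 5 fell (5 and 5 adjusted over the list alone, with adjusted p = 0.772), with RAB18 (AT5G66400, 2.06 ± 0.087) and RD29B (1.81 ± 0.10) among the rises. Of immunity and jasmonate genes, 2 of 16 rose and 7 fell (2 and 7 adjusted over the list alone, with adjusted p = 0.0821), with PR1 (AT2G14610, -1.80 ± 0.16) and WRKY70 (AT3G56400, -1.36 ± 0.27) among the falls. In total 9634 genes were called, 5972 higher and 3662 lower (62.0% higher), with 598 and 261 past 2-fold. The H3.1 call was lost without replicate 1 at 21 °C (adjusted p = 0.0575), and the auxin response call without replicate 2 at 27 °C (adjusted p = 0.068). With median-of-ratios scaling 4861 were higher and 4747 lower (50.6% higher).

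**Figure D2:**
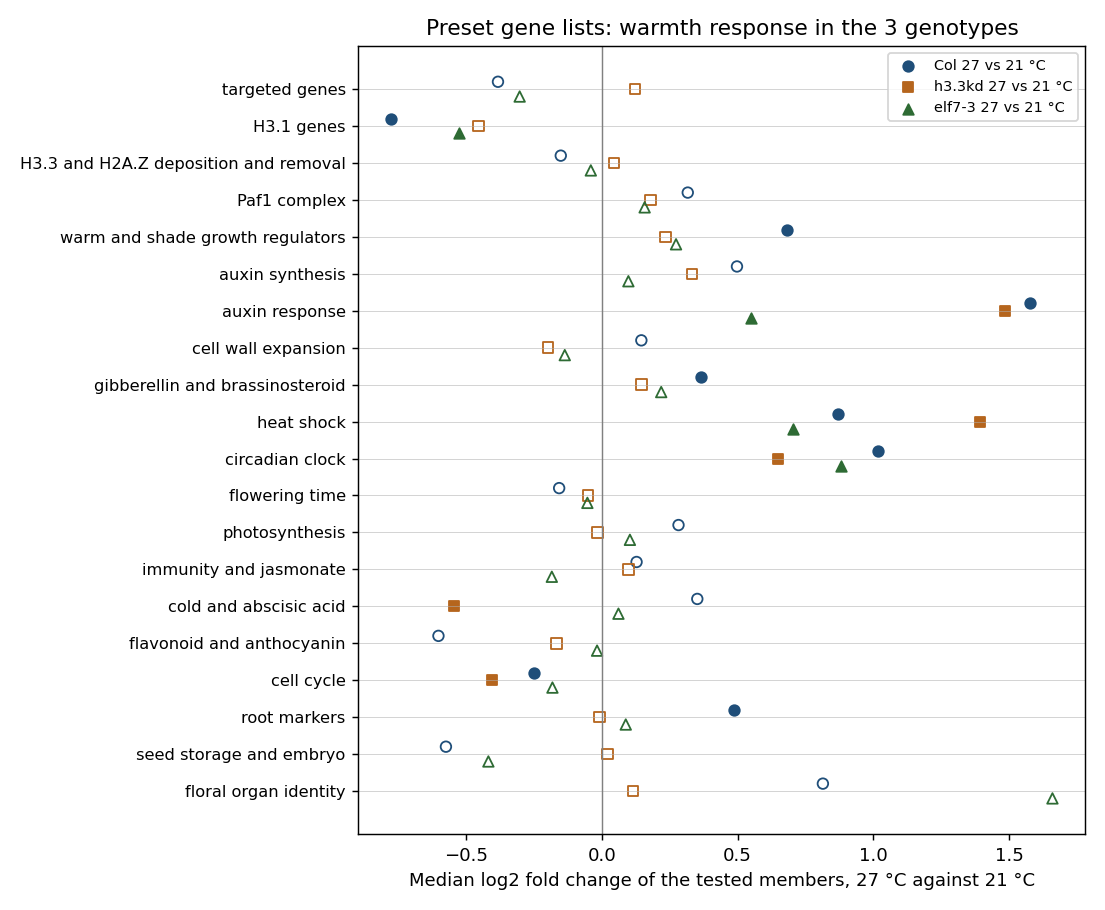
Median log2 fold change, 27 °C against 21 °C, of the tested members of each preset list (vertical axis) in Col, h3.3kd and elf7-3. Filled symbols had a camera adjusted p under 0.05. The auxin response median was 1.58 in Col, 1.48 in h3.3kd and 0.55 in elf7-3.

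The comparison of h3.3kd with Col at 21 °C asked what reduced H3.3 changes without warmth. All 5 H3.1 genes were higher (5 of 5 were higher and 0 were lower, or 5 and 0 adjusted over the list alone), with HTR3 (AT3G27360, 1.0 ± 0.17) and HTR2 (0.96 ± 0.088). H3.1 genes had adjusted p = 8.42e-05 by camera and adjusted p = 0.101 with an estimated correlation. The linker histone gene HIS1-3 (AT2G18050, 3.12 ± 0.12), known to respond to drought, was also among the largest rises, together with AT3G02480 (3.70 ± 0.17) and ECP63 (3.07 ± 0.14), late embryogenesis abundant proteins, AT2G05915 (3.62 ± 0.32), AT1G04560 (3.36 ± 0.13) and AT3G29633 (3.2 ± 0.28). Of cold and abscisic acid genes, 7 of 13 were higher and 2 were lower (7 and 2 adjusted over the list alone), with RD29B (2.17 ± 0.10), RD29A (AT5G52310, 1.87 ± 0.20) and RAB18 (1.86 ± 0.087). Cold and abscisic acid genes had adjusted p = 2.25e-04 by camera and adjusted p = 0.333 with an estimated correlation. Photosynthesis genes were higher: 15 of 25 were higher and 1 was lower (15 and 1 adjusted over the list alone), with LHCB1.2 (AT1G29910, 0.88 ± 0.13) and LHCB6 (AT1G15820, 0.58 ± 0.094). Photosynthesis genes had adjusted p = 2.87e-06 by camera and adjusted p = 0.38 with an estimated correlation. The largest falls were AZI1 (AT4G12470, -4.45 ± 0.20), a lipid-transfer protein of defence priming, AT2G25510 (-4.25 ± 0.29), HTR8, AT3G44970 (-3.91 ± 0.16), a cytochrome P450, AT5G18840 (-3.60 ± 0.23) and AT5G42530 (-3.38 ± 0.29). Of immunity and jasmonate genes, 0 of 16 were higher and 7 were lower (0 and 7 adjusted over the list alone, with camera adjusted p = 0.116), with PR5 (-2.36 ± 0.24), WRKY70 (-1.58 ± 0.27) and VSP2 (AT5G24770, -1.53 ± 0.24). Of cell wall expansion genes, 2 of 19 were higher and 10 were lower (2 and 10 adjusted over the list alone, with adjusted p = 0.0565), with XTH15 (AT4G14130, -2.62 ± 0.20) and XTH24 (AT4G30270, -1.5 ± 0.16), xyloglucan-modifying enzymes. Of flowering time genes, 1 of 14 was higher and 4 were lower (1 and 4 adjusted over the list alone, with adjusted p = 0.332), with SOC1 (1.02 ± 0.17) higher. Of seed storage and embryo genes, 3 of 13 were higher and 7 were lower (3 and 8 adjusted over the list alone, with adjusted p = 0.545), with SESA1 (-1.84 ± 0.46) lower and EM6 (AT2G40170, 1.78 ± 0.12) higher. In total 6725 genes were called, 2556 higher and 4169 lower (38.0% higher), with 251 and 464 past 2-fold. With median-of-ratios scaling 3336 were higher and 3265 lower (50.5% higher), and with voom on estimated reads 2919 and 4093.

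At 27 °C the H3.1 genes were again higher in h3.3kd than in Col (5 of 5 were higher and 0 were lower, or 5 and 0 adjusted over the list alone), with HTR3 (1.76 ± 0.17) and HTR2 (1.28 ± 0.088). H3.1 genes had adjusted p = 3.23e-04 by camera and adjusted p = 0.116 with an estimated correlation. AT3G53730 (3.52 ± 0.077), a histone H4 gene, and HIS1-3 (3.51 ± 0.12) were among the largest rises, with AT2G05915 (3.82 ± 0.32), AT1G09500 (3.75 ± 0.20), AT1G07450 (3.26 ± 0.19) and AT5G65980 (3.1 ± 0.18). The largest falls were AT3G05727 (-5.62 ± 0.17), M17 (AT2G41260, -5.45 ± 0.31), AT3G16670 (-5.13 ± 0.27), AT4G22490 (-4.92 ± 0.14), AZI1 (-4.27 ± 0.20) and MIOX2 (-4.26 ± 0.25). Of gibberellin and brassinosteroid genes, 1 of 20 was higher and 13 were lower (2 and 13 adjusted over the list alone), with GA2OX6 (-1.66 ± 0.14) and DWF4 (AT3G50660, -1.02 ± 0.065), a brassinosteroid synthesis enzyme. Gibberellin and brassinosteroid genes had adjusted p = 0.0124 by camera and adjusted p = 0.28 with an estimated correlation. Root markers were lower in the same libraries: 0 of 16 were higher and 11 were lower (0 and 11 adjusted over the list alone), with CASP5 (-1.89 ± 0.16), CASP2 (AT3G11550, -1.58 ± 0.13) and IRT1 (-1.16 ± 0.28). Root markers had adjusted p = 0.014 by camera and adjusted p = 0.355 with an estimated correlation. Auxin response genes went both ways (10 of 25 were higher and 8 were lower, or 10 and 8 adjusted over the list alone; adjusted p = 0.445): IAA6 (-1.86 ± 0.31) and IAA19 (-1.3 ± 0.19) were lower and SAUR22 (1.31 ± 0.28) and SAUR26 (AT3G03850, 1.27 ± 0.19) higher. Of auxin synthesis genes, 3 of 8 were higher and 5 were lower (3 and 5 adjusted over the list alone, with adjusted p = 0.743): YUC8 (-1.21 ± 0.26) and YUC9 (-0.83 ± 0.22) were lower and TAR2 (AT4G24670, 1.06 ± 0.17) higher. Among growth regulators (1 of 18 was higher and 5 were lower, or 1 and 5 adjusted over the list alone; adjusted p = 0.445), PIF4 (AT2G43010, -0.70 ± 0.12), the helix-loop-helix factor central to warm growth, and PIF5 (-0.89 ± 0.12) were lower. Of cell wall expansion genes, 3 of 19 were higher and 11 were lower (3 and 11 adjusted over the list alone, with adjusted p = 0.0876), XTH15 (-3.94 ± 0.20) and XTH17 (AT1G65310, -2.2 ± 0.18) falling. Of clock genes, 2 of 14 were higher and 7 were lower (2 and 7 adjusted over the list alone, with adjusted p = 0.479), with GI (-1.47 ± 0.17) and PRR7 (AT5G02810, -1.47 ± 0.20). In total 10384 genes were called, 4051 higher and 6333 lower (39.0% higher), with 424 and 932 past 2-fold. With median-of-ratios scaling 5390 were higher and 4909 lower (52.3% higher), and with voom on estimated reads 5157 and 5121.

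The comparison of elf7-3 with Col at 21 °C asked what loss of this Paf1 subunit changes without warmth. FLC (AT5G10140, -3.03 ± 0.20), on chromosome 5 from 3173382 to 3179448, and its relatives FLM (AT1G77080, -1.83 ± 0.12), MAF4 (AT5G65070, -1.35 ± 0.15) and MAF5 (AT5G65080, -0.98 ± 0.15), all floral repressors, were lower, and of the flowering time list 1 of 14 was higher and 7 were lower (1 and 7 adjusted over the list alone). Flowering time genes had adjusted p = 5.36e-04 by camera and adjusted p = 0.0586 with an estimated correlation. MAM1 (AT5G23010, -3.84 ± 0.28), CYP83A1 (AT4G13770, -3.40 ± 0.34) and CYP79F1 (AT1G16410, -2.65 ± 0.25), enzymes of aliphatic glucosinolate synthesis, were among the largest falls, with AT1G52100 (-2.59 ± 0.17) and AT5G33370 (-2.59 ± 0.22). Among the largest rises were AT4G09355 (7.05 ± 0.48), QQS (AT3G30720, 4.2 ± 0.22), a gene known to act on starch content, AT3G01345 (3.56 ± 0.25), AT2G13430 (2.87 ± 0.17) and AT1G27565 (2.72 ± 0.28). Root markers were higher: 8 of 16 were higher and 0 were lower (10 and 0 adjusted over the list alone), with IRT1 (1.86 ± 0.28), CASP5 (1.5 ± 0.16) and PIN2 (AT5G57090, 1.02 ± 0.13), a root auxin transporter. Root markers had adjusted p = 2.41e-05 by camera and adjusted p = 0.15 with an estimated correlation. Of H3.3 and H2A.Z deposition genes, 3 of 15 were higher and 3 were lower (3 and 3 adjusted over the list alone, with adjusted p = 0.836), among them PIE1 (AT3G12810, -0.48 ± 0.073), the ATPase of the complex that deposits H2A.Z, and HTA11 (AT3G54560, 0.50 ± 0.084), an H2A.Z gene. Growth regulators FHL (AT5G02200, -0.97 ± 0.18) and HFR1 (-0.96 ± 0.12) were lower (2 of 18 were higher and 6 were lower, or 2 and 6 adjusted over the list alone; adjusted p = 0.523), as were COR6.6 (AT5G15970, -1.36 ± 0.29) and COR15B (-1.19 ± 0.30) of the cold and abscisic acid list (2 of 13 were higher and 3 were lower, or 2 and 3 adjusted over the list alone; adjusted p = 0.792). Of flavonoid genes, 0 of 10 were higher and 4 were lower (0 and 4 adjusted over the list alone, with adjusted p = 0.369), with FLS1 (AT5G08640, -1.05 ± 0.23) and CHS (AT5G13930, -1.05 ± 0.13) lower. In total 5751 genes were called, 2660 higher and 3091 lower, with 222 and 178 past 2-fold. With median-of-ratios scaling 2985 were higher and 2978 lower. Past 2-fold, a pseudocount of 0.1 gave 426 and 307, and voom on estimated reads 530 and 315.

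At 27 °C auxin response genes were lower in elf7-3 than in Col: 0 of 25 were higher and 19 were lower (0 and 20 adjusted over the list alone). Auxin response genes had adjusted p = 2.11e-10 by camera and adjusted p = 0.0572 with an estimated correlation. IAA29 (-2.61 ± 0.20), SAUR22 (-2.08 ± 0.28) and GH3.3 (-1.57 ± 0.16) were among the larger differences. YUC8 (-2.28 ± 0.26), YUC9 (-1.47 ± 0.22) and YUC2 (-1.34 ± 0.14) were lower among auxin synthesis genes (1 of 8 was higher and 4 were lower, or 2 and 4 adjusted over the list alone; adjusted p = 0.164). Of the warm and shade growth regulators, 0 of 18 were higher and 9 were lower (0 and 9 adjusted over the list alone), with FHL (-1.49 ± 0.18), HFR1 (-1.49 ± 0.12), HB4 (AT2G44910, -1.12 ± 0.18) and HB2 (AT4G16780, -0.77 ± 0.12), the latter pair shade-induced homeobox genes. Warm and shade growth regulators had adjusted p = 0.00229 by camera and adjusted p = 0.0375 with an estimated correlation. Flowering time genes were lower (1 of 14 was higher and 9 were lower, or 1 and 9 adjusted over the list alone), FLC (-3.05 ± 0.20) and FLM (-1.71 ± 0.12) the most, while SOC1 (1.41 ± 0.17) was higher. Flowering time genes had adjusted p = 0.00437 by camera and adjusted p = 0.0572 with an estimated correlation. Of cell cycle genes, 10 of 19 were higher and 0 were lower (10 and 0 adjusted over the list alone), with CYCB1;1 (0.64 ± 0.15) and CDKB1;1 (AT3G54180, 0.56 ± 0.14). Cell cycle genes had adjusted p = 0.00531 by camera and adjusted p = 0.456 with an estimated correlation. Of photosynthesis genes, 4 of 25 were higher and 11 were lower (4 and 11 adjusted over the list alone), with LHCB2.2 (AT2G05070, -1.67 ± 0.19) and LHCB4.2 (-1.03 ± 0.15). Photosynthesis genes had adjusted p = 0.0391 by camera and adjusted p = 0.652 with an estimated correlation. The largest falls were AT5G44440 (-4.46 ± 0.37), FLC, AT1G52100 (-2.82 ± 0.17), AT5G22500 (-2.76 ± 0.27), AT1G06080 (-2.69 ± 0.21), a fatty acid desaturase, and IAA29. The largest rises were AT4G09355 (7.14 ± 0.48), AT5G23115 (4.59 ± 1.11), QQS (4.18 ± 0.22), AT1G30250 (3.61 ± 0.45), AT3G55566 (3.28 ± 0.44) and AT3G01345 (3.11 ± 0.25). PIE1 (-0.75 ± 0.073) was lower and HTA11 (0.40 ± 0.084) higher, as at 21 °C. In total 6988 genes were called, 3284 higher and 3704 lower, with 159 and 248 past 2-fold. The larger side turned with median-of-ratios scaling, to 3696 higher and 3404 lower, and with voom on estimated reads, to 3879 and 3535. The photosynthesis call was lost without Col replicate 2 (adjusted p = 0.121) or elf7-3 replicate 1 (adjusted p = 0.135), with a filter at 5 TPM (adjusted p = 0.0525) and with median-of-ratios scaling (adjusted p = 0.0582).

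**Figure D3:**
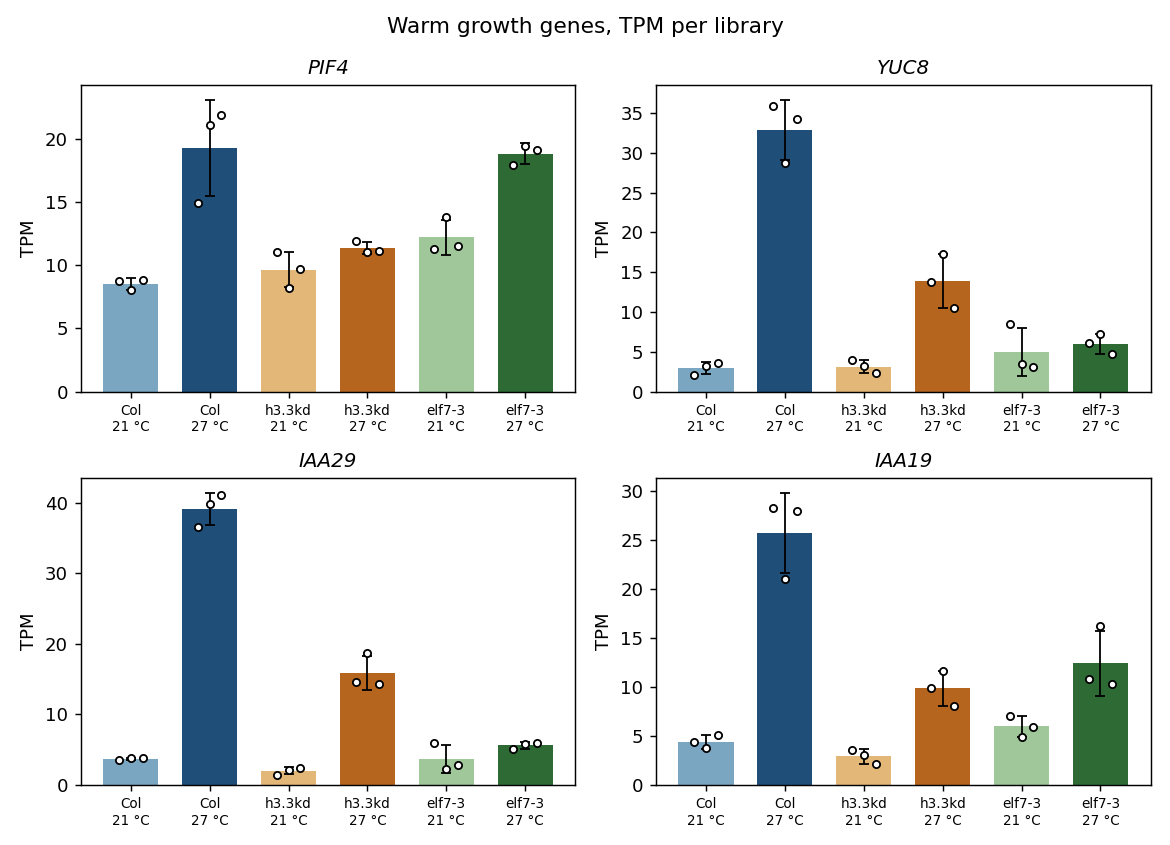
TPM of PIF4, YUC8, IAA29 and IAA19 in each of the 6 groups. Bars are means, lines are SDs and circles the 3 libraries. At 27 °C, YUC8 averaged 32.9 ± 3.77 TPM (SD) in Col, 13.9 ± 3.41 in h3.3kd and 6.02 ± 1.3 in elf7-3.

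The interaction tests asked whether the warmth response itself differed from that of Col. In elf7-3 it was more negative for auxin response genes: 0 of 25 responded more positively and 11 responded more negatively (0 and 15 adjusted over the list alone). Auxin response genes had adjusted p = 7.87e-12 by camera and adjusted p = 0.0316 with an estimated correlation. IAA29 (-2.52 ± 0.28), SAUR22 (-2.42 ± 0.39), IAA1 (AT4G14560, -1.41 ± 0.18) and IAA19 (-1.38 ± 0.26) had the largest differences. YUC8 (-2.77 ± 0.37), YUC9 (-1.74 ± 0.31) and YUC2 (-1.24 ± 0.20) also responded more negatively (0 of 8 responded more positively and 3 responded more negatively, or 1 and 3 adjusted over the list alone). Auxin synthesis genes had adjusted p = 0.00481 by camera and adjusted p = 0.17 with an estimated correlation. Of growth regulators, 0 of 18 responded more positively and 2 responded more negatively (0 and 5 adjusted over the list alone), with PRE6 (-1.09 ± 0.22) the largest. Warm and shade growth regulators had adjusted p = 0.00438 by camera and adjusted p = 0.0316 with an estimated correlation. Root markers moved with them: 0 of 16 responded more positively and 6 responded more negatively (0 and 8 adjusted over the list alone), with IRT1 (-1.90 ± 0.39), CASP5 (-1.73 ± 0.23) and CASP4 (-1.66 ± 0.29). Root markers had adjusted p = 2.74e-08 by camera and adjusted p = 0.0316 with an estimated correlation. Gibberellin and brassinosteroid genes (0 of 20 responded more positively and 4 responded more negatively, or 1 and 7 adjusted over the list alone) included GA2OX6 (-2.22 ± 0.20). Gibberellin and brassinosteroid genes had adjusted p = 0.00306 by camera and adjusted p = 0.124 with an estimated correlation. Photosynthesis genes (1 of 25 responded more positively and 5 responded more negatively, or 1 and 8 adjusted over the list alone) included LHCB2.1 (-1.3 ± 0.17). Photosynthesis genes had adjusted p = 3.22e-04 by camera and adjusted p = 0.411 with an estimated correlation. Immunity genes (0 of 16 responded more positively and 2 responded more negatively, or 1 and 5 adjusted over the list alone) went the same way, and cell cycle genes as a list the other way with no single gene called (0 of 19 responded more positively and 0 responded more negatively, or 0 and 0 adjusted over the list alone). Immunity and jasmonate genes had adjusted p = 0.0248 by camera and adjusted p = 0.113 with an estimated correlation. Cell cycle genes had adjusted p = 0.0237 by camera and adjusted p = 0.411 with an estimated correlation. Flavonoid genes were also more positive (2 of 10 responded more positively and 1 responded more negatively, or 4 and 1 adjusted over the list alone), with FLS1 (1.38 ± 0.33) and CHS (1.14 ± 0.19). Flavonoid genes had adjusted p = 0.00438 by camera and adjusted p = 0.142 with an estimated correlation. Of the heat shock genes, 0 of 23 responded more positively and 1 responded more negatively (0 and 1 adjusted over the list alone, with adjusted p = 0.0586). The most positive differences were MAM1 (2.96 ± 0.40), BCAT4 (AT3G19710, 2.59 ± 0.45), IMD1 (AT5G14200, 2.44 ± 0.36) and CYP83A1 (2.43 ± 0.48), of glucosinolate synthesis, BIP3 (2.43 ± 0.30) and AT5G33370 (2.33 ± 0.31). The most negative were AT5G44440 (-4.51 ± 0.53), AT5G22500 (-3.66 ± 0.38), AT1G06080 (-3.2 ± 0.30), AT2G25510 (-2.96 ± 0.41), AT5G02540 (-2.95 ± 0.31) and YUC8. In total 1454 genes were called, 751 more positive and 703 more negative, with 93 and 190 past 2-fold. The larger side turned with only the groups compared (759 and 816), without Col replicate 1 at 21 °C (495 and 526) and without elf7-3 replicate 2 at 27 °C (649 and 727). The immunity call was lost without elf7-3 replicate 1 at 27 °C (adjusted p = 0.0577), and with a pseudocount of 0.1, a filter at 5 TPM or voom on estimated reads (adjusted p = 0.0836 to 0.175). The cell cycle call was lost without Col replicate 2 or elf7-3 replicate 2 at 27 °C or elf7-3 replicate 3 at 21 °C (adjusted p = 0.0627, 0.125 and 0.0793).

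In h3.3kd the interaction called 3689 genes, 1679 more positive and 2010 more negative, with 215 and 317 past 2-fold. The larger side turned with median-of-ratios scaling, to 2004 more positive and 1715 more negative, with voom on estimated reads, to 2172 and 1499, and without h3.3kd replicate 1 at 27 °C, to 1631 and 1539. Auxin response genes were not called as a list, with a median of 0.42 (4 of 25 responded more positively and 3 responded more negatively, or 6 and 5 adjusted over the list alone; adjusted p = 0.302): GH3.17 (AT1G28130, -0.87 ± 0.10) responded more negatively and SAUR24 (1.32 ± 0.28) more positively. YUC9 (-1.38 ± 0.31), YUC8 (-1.3 ± 0.37) and YUC2 (-0.85 ± 0.20) responded more negatively (0 of 8 responded more positively and 3 responded more negatively, or 1 and 4 adjusted over the list alone; adjusted p = 0.264), as did PIF5 (-0.98 ± 0.17) and PIF4 (-0.85 ± 0.18) (0 of 18 responded more positively and 4 responded more negatively, or 0 and 4 adjusted over the list alone; adjusted p = 0.0826). Of gibberellin and brassinosteroid genes, 0 of 20 responded more positively and 7 responded more negatively (0 and 8 adjusted over the list alone), with GA2OX6 (-1.58 ± 0.20) and DWF4 (-0.86 ± 0.091). Gibberellin and brassinosteroid genes had adjusted p = 0.0125 by camera and adjusted p = 0.239 with an estimated correlation. Clock genes (0 of 14 responded more positively and 5 responded more negatively, or 0 and 6 adjusted over the list alone) included LNK2 (AT3G54500, -1.16 ± 0.28) and LUX (-0.77 ± 0.10), and photosynthesis genes (0 of 25 responded more positively and 7 responded more negatively, or 0 and 9 adjusted over the list alone) LHCB2.1 (-0.79 ± 0.17). Clock genes had adjusted p = 0.0241 by camera and adjusted p = 0.239 with an estimated correlation. Photosynthesis genes had adjusted p = 0.0147 by camera and adjusted p = 0.587 with an estimated correlation. Of cold and abscisic acid genes, 0 of 13 responded more positively and 5 responded more negatively (0 and 6 adjusted over the list alone), with RD29B (-2.17 ± 0.15) and RAB18 (-1.82 ± 0.12). Cold and abscisic acid genes had adjusted p = 0.00159 by camera and adjusted p = 0.302 with an estimated correlation. Of root markers, 0 of 16 responded more positively and 6 responded more negatively (1 and 12 adjusted over the list alone), with CASP5 (-2.45 ± 0.23) and IRT1 (-2.04 ± 0.39). Root markers had adjusted p = 8.11e-04 by camera and adjusted p = 0.239 with an estimated correlation. Heat shock genes were not called as a list (6 of 23 responded more positively and 2 responded more negatively, or 6 and 2 adjusted over the list alone; adjusted p = 0.122), while HSP17.6A (3.53 ± 0.44) and HSP17.6II (AT5G12020, 1.52 ± 0.38) rose more in h3.3kd. Seed storage genes (6 of 13 responded more positively and 2 responded more negatively, or 8 and 2 adjusted over the list alone; adjusted p = 0.0826) included CRC (AT4G28520, 3.22 ± 0.41). The most positive differences also held AT5G42530 (3.62 ± 0.41), TGG2 (AT5G25980, 3.57 ± 0.20), a myrosinase, and SESA5 (AT5G54740, 3.45 ± 0.52). The most negative were AT1G06080 (-3.71 ± 0.30), AT1G47980 (-3.39 ± 0.23), AT5G22500 (-3.23 ± 0.38), AT1G04660 (-3.12 ± 0.37), MIOX2 (-3.05 ± 0.35) and AT3G16670 (-3.03 ± 0.39). The YUC8 call was lost without Col replicate 1 or h3.3kd replicate 1 at 21 °C, or Col replicate 3 or h3.3kd replicate 3 at 27 °C (-1.23 to -1.09), and with voom on estimated reads (-1.26, adjusted p = 0.0501). The clock and photosynthesis calls were lost without Col replicate 2 at 27 °C (adjusted p = 0.0554 for both), the clock call also without h3.3kd replicate 2 at 27 °C (adjusted p = 0.0538) and with a filter at 5 TPM (adjusted p = 0.0647), and the photosynthesis call also without Col replicate 1 or h3.3kd replicate 3 at 21 °C (adjusted p = 0.0673 and 0.11). When genotypes were relabelled within temperature, as planned, 8 of 100 relabellings gave as many calls as the h3.3kd interaction and 4 of 100 as many as the elf7-3 interaction, the real one included in each. All the others with as many mixed the genotypes unequally between temperatures, so that the difference between genotypes entered the test, which therefore decided for neither. With the additive genotype and temperature differences removed, a test chosen after seeing this, only the real labelling gave as many. The real counts and highest others were 3500 and 1 in h3.3kd and 1548 and 16 in elf7-3.

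The 2 mutants were then compared with each other. At 27 °C, 1321 genes were higher and 1879 lower in both mutants against Col, 3200 in all, where independent calls would give 664 and 1170. Another 1144 were called in opposite directions, against 1786. Across genes, the fold changes of both mutants had a Pearson correlation of 0.240 and a covariance of 0.0506, against 0.50 and 0.0111 in simulated unchanged groups that shared the same Col libraries. At 21 °C, 580 genes were higher and 1043 lower in both, 1623 in all, where independent calls would give 339 and 643, and 783 went in opposite directions, against 947. The correlation there was 0.182 and the covariance 0.0281, against 0.50 and 0.0112 in simulated unchanged groups. For the interactions, 747 genes differed from Col in the same direction in both mutants, 424 more positive and 323 more negative, against 62.9 and 70.5 for independent calls, and 43 went in opposite directions. Their correlation was 0.439 and their covariance 0.0675, against 0.50 and 0.0223 in simulated groups. All 3 correlations thus lay below, and all 3 covariances above, those of unchanged groups. Without Col replicate 3 at 27 °C the shared interaction calls numbered 497. YUC8, YUC9, YUC2, GA2OX6, IRT1, CASP5, AT5G22500 and AT1G06080 were among the genes with a more negative response in both mutants. Shared Col libraries alone give a positive correlation, so the overlap is not independent evidence from each mutant.

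To compare the size of the warmth response without choosing genes in Col, genes called in elf7-3 were measured in Col and h3.3kd. The 5972 genes that rose in elf7-3 had a median rise of 0.43 in Col and 0.31 in h3.3kd, and 68.2% of them rose less in h3.3kd (camera p = 2.12e-06, and p = 0.055 with an estimated correlation). The 3662 that fell had medians of -0.44 and -0.33, and 61.7% fell less in h3.3kd (p = 2.45e-07, and p = 0.0274 with an estimated correlation). Among genes past 2-fold in elf7-3, the 598 rises had medians of 1.22 in Col and 0.93 in h3.3kd (p = 9.89e-06, and p = 0.0803 with an estimated correlation). The 261 falls had medians of -1.08 and -0.76 (p = 1.63e-06, and p = 0.0122 with an estimated correlation). For the 5240 genes that rose in h3.3kd, the medians were 0.46 in Col and 0.40 in elf7-3 (p = 0.00299, and p = 0.13 with an estimated correlation). For the 3952 that fell they were -0.35 and -0.31 (p = 0.00497, and p = 0.193 with an estimated correlation). The 754 genes that rose past 2-fold in h3.3kd had medians of 1.03 in Col and 0.84 in elf7-3 (p = 7.55e-06, and p = 0.0285 with an estimated correlation). The 337 falls past 2-fold had medians of -0.82 and -0.72 (p = 0.0277, and p = 0.23 with an estimated correlation). Genes are not independent replicates, so these medians describe the gene sets in these libraries.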

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

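The tests on organelle genes, on root markers and on the scaling of the h3.3kd calls, and the relabelling of values with additive differences removed, were chosen only after the result was seen. The other splits and the share of the most abundant genes were set beforehand.

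A test of the difference itself marked the warmth response as different from Col for 3689 genes in h3.3kd and 1454 in elf7-3. Among the 12 libraries of Col and h3.3kd fitted alone, 3511 genes were called, and relabelling genotypes within temperature gave as many in 8 of 100 relabellings, the real one included, so that this test did not exclude chance. The highest other count was 11016. For elf7-3 the real count was 1575, 4 of 100 relabellings gave as many, and the highest other was 8982. Counts several times the real one point to a structure of the samples: all 7 and all 3 of the other relabellings with as many calls mixed the genotypes unequally between temperatures (11 of the 100 did), so that the difference between genotypes itself entered the test. The share of relabellings therefore decides for neither mutant, though that of elf7-3 was under the 0.05 set beforehand. With the additive genotype and temperature differences removed, 1 of 100 relabellings gave as many in each, the real one. The real calls were 3500 against 1 in h3.3kd and 1548 against 16 in elf7-3. The differences removed were estimated with the real labels. This argues against a chance assignment of these libraries, but not against differences in how the groups were grown, as the labels give no batch. For the 7 comparisons of 2 groups, 10 splits of 6 libraries are too few for a share under 0.05, and the real split was the only 1 of 10 with as many calls. The real counts and the highest others were 11182 and 1 for warmth in Col, 8047 and 0 in h3.3kd and 8951 and 0 in elf7-3. They were 6539 and 0 for h3.3kd against Col at 21 °C, 9380 and 0 at 27 °C, 5524 and 0 for elf7-3 at 21 °C and 6283 and 0 at 27 °C.

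In elf7-3, 10 preset lists differed from Col in warmth response by camera. Their median differences (log2) were -0.90 for auxin response, -0.61 for root markers, -0.44 for auxin synthesis and -0.40 for warm and shade growth regulators. They were -0.39 for immunity, -0.20 for gibberellin and brassinosteroid, -0.18 for photosynthesis, 0.21 for cell cycle, 0.47 for flavonoid, and 0.85 for the 2 floral genes (adjusted p = 0.0409, and adjusted p = 0.127 with an estimated correlation). The floral call was also lost without Col replicate 1 or 3 at 21 °C, elf7-3 replicate 1 or 3 at 21 °C or elf7-3 replicate 1 at 27 °C (adjusted p = 0.0558 to 0.0975), and with a pseudocount of 0.1, a filter at 5 TPM, library weights or voom (adjusted p = 0.0567 to 0.238). With an estimated correlation auxin response, root markers and growth regulators held (adjusted p = 0.0316 each). Auxin synthesis (0.17), immunity (0.113), gibberellin and brassinosteroid (0.124), photosynthesis (0.411), cell cycle (0.411) and flavonoid (0.142) did not. Named genes whose own difference was called were AT5G44440 -4.51, AT5G22500 -3.66, AT1G06080 -3.2, AT2G25510 -2.96, AT5G02540 -2.95, YUC8 -2.77, IAA29 -2.52, SAUR22 -2.42 and GA2OX6 -2.22 on the negative side. Smaller negative differences were IRT1 -1.90, YUC9 -1.74, CASP5 -1.73, CASP4 -1.66, IAA1 -1.41, IAA19 -1.38, LHCB2.1 -1.3, YUC2 -1.24 and PRE6 -1.09. On the positive side were MAM1 2.96, BCAT4 2.59, IMD1 2.44, CYP83A1 2.43, BIP3 2.43, AT5G33370 2.33, FLS1 1.38 and CHS 1.14.

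In h3.3kd, 6 lists differed, with medians of 0.51 for the targeted genes, -0.64 for root markers, -0.32 for cold and abscisic acid, -0.29 for gibberellin and brassinosteroid, -0.23 for the clock and -0.18 for photosynthesis. None of the 6 held with an estimated correlation (adjusted p = 0.239 to 0.587). Named genes with a called negative difference were AT1G06080 -3.71, AT1G47980 -3.39, AT5G22500 -3.23, AT1G04660 -3.12, MIOX2 -3.05, AT3G16670 -3.03, CASP5 -2.45 and RD29B -2.17. Further ones were IRT1 -2.04, RAB18 -1.82, GA2OX6 -1.58, YUC9 -1.38, YUC8 -1.3, LNK2 -1.16, PIF5 -0.98, GH3.17 -0.87, DWF4 -0.86, PIF4 -0.85, YUC2 -0.85, LHCB2.1 -0.79 and LUX -0.77. Those with a positive difference were AT5G42530 3.62, TGG2 3.57, HSP17.6A 3.53, SESA5 3.45, CRC 3.22, HSP17.6II 1.52, SAUR24 1.32, HTR8 0.74, HTR4 0.61 and HTR5 0.40.

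More genes were called lower than higher in h3.3kd, at 27 °C 6333 against 4051. With median-of-ratios scaling 52.3% of the calls at 27 °C were higher, but that scaling centres the genes and so all but fixes this share, and of the 8960 genes called both ways 0 changed direction. With voom on estimated reads 50.2% were higher at 27 °C and 41.6% at 21 °C. The 100 most abundant genes held 20.9% to 22.1% of all TPM in h3.3kd at 27 °C and 20.4% to 20.9% in Col, so that the lowest h3.3kd library lay -0.035 percentage points from the highest Col library, an overlap far smaller than the SD of 0.641 between the h3.3kd libraries. At 21 °C the shares did not overlap, with 22.3% to 24.1% in h3.3kd and 20.8% to 22% in Col. Past 2-fold, a split that centring does not fix, lower genes stayed more numerous in h3.3kd. With median-of-ratios scaling 524 were higher and 769 lower at 27 °C, and 277 and 409 at 21 °C. With voom they were 733 and 1241 at 27 °C, and 424 and 766 at 21 °C. This argues against the scaling as the source of the split past 2-fold. For the split over all calls, a composition effect, a few abundant genes or a loss of expression with less H3.3 cannot be told apart. TPM carry no outside reference for it.

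Organelle genes were higher at 27 °C in h3.3kd: 101 of 127 tested genes rose, with a median of 1.81. In replicate 1 at 27 °C, which also had the fewest estimated reads, they took 3.66% of all TPM. Without it 81 rose and the median was 1.05, between the bounds set for that library as the whole source and as no source. Chloroplast genes went from 1.89 to 0.69 (0.74 in Col) and mitochondrial genes from 1.68 to 1.47 (0.98 in Col). The other 2 libraries at 27 °C had 1.03 times the mean reads at 21 °C, which argues against low depth as the source of the rise that stayed without replicate 1. For replicate 1 itself depth stays open: the library with the fewest reads had the highest organelle share in 2 of 6 groups, as many as chance gives, but these were the 2 groups of h3.3kd. A difference in RNA preparation of 1 library may account for part, and an effect of the genotype stays open, as 3 libraries cannot separate them. The share had exact two-sided permutation p = 0.1 for warmth in h3.3kd and in Col, the smallest that 3 against 3 allow, and p = 0.4 for h3.3kd against Col at 27 °C.

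Root markers responded less to warmth in both mutants, with medians of -0.64 in h3.3kd and -0.61 in elf7-3 and 6 of 16 called in each. With an estimated correlation the list held in elf7-3 (adjusted p = 0.0316) but not in h3.3kd (adjusted p = 0.239). A smaller share of root tissue was predicted to lower all 16 markers by about the same amount in the warm mutant libraries. That holds only if each marks the whole root and nothing else. The markers differed far beyond their errors, with a heterogeneity of 11 per degree of freedom in h3.3kd and 9.14 in elf7-3. The pseudocount of 1 shrinks changes of markers at low levels, and markers of different root parts can move apart. The heterogeneity therefore cannot decide against a smaller share. In elf7-3 all 16 were negative (-1.90 to -0.026), as a smaller share would give, and in h3.3kd they ranged from -2.45 to 0.39. The levels differed between the mutants. In h3.3kd the markers were lower than in Col at 27 °C, 11 of 16 with 0 higher (median -0.73), and at 21 °C 3 were higher and 2 lower (median -0.11). In elf7-3 they were higher at 21 °C, 8 of 16 with 0 lower (median 0.53), and at 27 °C 2 were higher and 4 lower (median -0.17). With median-of-ratios scaling the medians were -0.60 and -0.61, which argues against the scaling. What set the levels, a larger root share in elf7-3 at 21 °C included, was not tested and stays open, as roots were not sampled apart.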

How the results depend on the processing

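The fits on estimated reads were chosen only after the data were seen; the other alternatives were set before the data were examined. Of 13 comparisons and 253 settings, 243 stayed within 1.5 times the count. With median-of-ratios scaling the larger side of the calls turned from lower to higher in h3.3kd against Col (38.0% to 50.5% higher at 21 °C, 39.0% to 52.3% at 27 °C). With voom it turned at 27 °C (50.2%) but not at 21 °C (41.6%). In elf7-3 it turned with median-of-ratios scaling (46.3% to 50.1% at 21 °C, 47.0% to 52.1% at 27 °C), and with voom at 27 °C (52.3%) but not at 21 °C (49.8%). The h3.3kd interaction turned from 45.5% to 53.9%, to 59.2% with voom and to 51.5% without h3.3kd replicate 1 at 27 °C. The elf7-3 interaction turned from 51.7% to 48.2% with only the groups compared, and to 48.5% and 47.2% without Col replicate 1 at 21 °C or elf7-3 replicate 2 at 27 °C. Requiring a 2-fold change besides the adjusted p gave fewer genes by construction: 1322 for warmth in Col, 1091 in h3.3kd, 859 in elf7-3. With a pseudocount of 0.1 these 2-fold counts were 1987, 1752 and 1419, and with voom 1968, 1593 and 1390. In the main fit the 2-fold rule gave 715 and 1356 for h3.3kd against Col at 21 and 27 °C, 400 and 407 for elf7-3, 532 for the h3.3kd and 283 for the elf7-3 interaction. With a pseudocount of 0.1 they were 1177 and 2027, 733 and 688, 660 and 299. With voom they were 1190 and 1974, 845 and 733, 625 and 351. The 2-fold counts thus depend on the pseudocount and on the fit, and the range of 1.5 times above does not cover them. Leaving out 1 library gave 9795 to 10377 genes for warmth in Col, 7972 to 8391 in h3.3kd, 8452 to 8882 in elf7-3. It gave 5306 to 6035 and 9035 to 9612 for h3.3kd against Col at 21 and 27 °C, 4463 to 5023 and 5645 to 6084 for elf7-3. The interactions ranged from 2801 to 3557 in h3.3kd and from 1005 to 1376 in elf7-3. The calls shared by both mutants ranged from 2381 to 3059 at 27 °C and from 497 to 783 for the interactions, lowest without Col replicate 3 at 27 °C; the cause was not tested. The differences in response of genes chosen in the remaining genotype ranged from -0.128 to -0.0978 in h3.3kd and from -0.0588 to -0.0395 in elf7-3.

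Replicate numbers did not pair the libraries, since the residuals of 21 pairs of the same number had correlations of -0.154 to 0.080. With a replicate block nonetheless, 10908 genes were called for warmth in Col, 9010 in h3.3kd, 9505 in elf7-3. The block gave 6525 and 10215 for h3.3kd against Col, 5559 and 6763 for elf7-3, and 3447 and 1352 for the interactions. It gave 3092 and 694 shared calls and differences in response of -0.112 and -0.0492.

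Of 48 called list results under 864 settings, 76 fell below the threshold and 0 turned: 38 with an estimated correlation, 21 without 1 library and 17 in other settings, 6 of them with a filter at 5 TPM and 4 with a pseudocount of 0.1. Of 300 values of named genes under 4821 settings, 12 calls were lost and 2 were gained. Another 2 values near 0 that were not called changed sign. They were HTR5 for warmth in h3.3kd, -0.045 to 0.0034 without 1 library and positive without replicate 2 at 21 °C, and ELF7 in h3.3kd at 21 °C, 0.00088 with median-of-ratios scaling. The cause was not tested. Simulated changes of log2 1 were found in 72% to 95% of genes and of log2 0.5 in 31% to 68%. Smaller changes were thus missed more often in that simulation. Only 200 of 20048 genes were changed there, and the adjusted p is stricter with so few. These shares therefore do not give what the real comparisons missed.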

Other observations

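The grouping of genes by annotated product was chosen only after the results above were seen. The tests of gene length, chromosome segments and glucosinolate genes were fixed before their results were seen, but the glucosinolate list was raised by the largest changes in elf7-3.

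Among 257 product families with at least 8 tested genes, histone genes moved as a group. In Col 0 of 31 rose and 23 fell at 27 °C (median -0.56; adjusted p = 3.28e-09 by camera and adjusted p = 0.14 with an estimated correlation). Against Col, h3.3kd had 24 of 31 higher and 3 lower at 21 °C (median 0.68; adjusted p = 2.11e-11 and adjusted p = 0.107 with an estimated correlation) and 25 higher and 3 lower at 27 °C (0.95; adjusted p = 3.82e-10 and adjusted p = 0.303 with an estimated correlation). Many histone genes are near-identical in sequence, so values of single members are uncertain. Late embryogenesis abundant proteins, known from drying seeds, had 7 of 11 genes higher in h3.3kd at 21 °C (median 1.82; adjusted p = 2.28e-08 and adjusted p = 0.107 with an estimated correlation), and 7 of 11 responded more negatively to warmth than in Col (-1.44; adjusted p = 0.000175 and adjusted p = 0.314 with an estimated correlation).

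Small nuclear ribonucleoprotein genes, which encode splicing components, fell in warm Col, 19 of 22 with 0 rising (median -0.51; adjusted p = 2.67e-07, and adjusted p = 0.00708 with an estimated correlation). Of 49 TIR-NBS-LRR disease resistance genes, 33 rose and 0 fell in warm Col (0.47, camera adjusted p = 3.87e-05). In warm elf7-3 29 rose and 4 fell (0.44, adjusted p = 0.00121). Against Col, elf7-3 had 2 higher and 26 lower at 27 °C (-0.31, adjusted p = 1.54e-05). At 21 °C these were 2 and 21 (-0.19, adjusted p = 0.0051). L7Ae ribosomal protein genes fell in warm Col, 11 of 11 (-0.67, adjusted p = 1.33e-06). Against Col, elf7-3 had 5 higher and 0 lower at 21 °C (0.21, adjusted p = 0.0205). At 27 °C all 11 were higher (0.49, adjusted p = 8.3e-07). In h3.3kd 7 were higher and 0 lower at 27 °C (0.26, adjusted p = 0.0115). Neither of the latter families held with an estimated correlation (adjusted p = 0.326 to 0.818). These directions were the same with median-of-ratios scaling.

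A hypothesis was that the whole aliphatic glucosinolate pathway is lower in elf7-3 at 21 °C and that this is lost at 27 °C. Of the 16 tested pathway genes that had not raised it, 9 were lower and 0 higher in elf7-3 at 21 °C (camera p = 6.22e-05, and p = 0.149 with an estimated correlation). At 27 °C 3 were higher and 2 lower. Their median difference in warmth response was 0.503, barely over the 0.5 set as the bound, with 6 called and camera p = 6.77e-09, or p = 0.0453 with an estimated correlation. Much of this came from Col, where warmth lowered 8 and raised 3 of the 16 (median -0.448), against a median of 0.236 in elf7-3, with 7 higher and 3 lower. Genes of all 21 tested members with a called difference included MAM1 2.96, BCAT4 2.59, IMD1 2.44 and CYP83A1 2.43. Of the 16, all but the 9 lower ones were not called at 21 °C. The values thus go with such a response in a part of the pathway rather than the whole. The same libraries raised and tested it.

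A hypothesis was that long genes lose more expression without ELF7 or with less H3.3. Across 19921 genes, Spearman's rho between exon length and log2 fold change was -0.143 in elf7-3 at 21 °C and -0.207 at 27 °C, under the bound of -0.1. In h3.3kd it was -0.0818 at 21 °C, over that bound, and -0.236 at 27 °C. Warmth gave rho of 0.261 in Col, 0.251 in elf7-3 and 0.133 in h3.3kd, so a relation with length also arose without a mutant. RNA integrity or library preparation that differs between groups could give the same trend and was not tested. Genes are not independent replicates.

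A chromosome segment from another background would put many changed genes side by side. Of 119 genes changed past 2-fold in elf7-3 at both temperatures, at most 3 lay within 50 tested neighbours, and 4 neighbouring pairs were seen, against a mean of 0.667 and a highest of 4 in 1000 shuffles. Of 403 in h3.3kd, at most 7 did, on chromosome 5 from 17742765 to 17989338 (TAIR10.1), with 31 neighbouring pairs against a mean of 8.12 and a highest of 20. The bound of 10 genes was met in neither, which argues only against a segment dense in genes changed this much. The excess of neighbours over the mean of the shuffles, in h3.3kd also over the highest, was not explained in either mutant.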
